A study of Mus musculus with 23 samples.

How the data were processed

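Both platforms measured the same 3 groups, saline, MPTP 24 h and MPTP 7 d, each sample a pool of 6 mice. Per the labels' protocols total RNA was isolated with Trizol, and for Affymetrix it was labelled with biotin using an Enzo in vitro transcription kit. Per the submitters' processing notes RMA was run on 12 arrays and MAS 5 on 4. The titles and descriptions also name dChip and SAM. Which of these produced the analysed Affymetrix table, the software versions, and the processing of the CodeLink arrays are not given in the sources used here.

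The unit of the Affymetrix values was read as log2 as deposited, from their range of 8.04 to 15.44, since the labels do not state a scale, and they were not transformed. The CodeLink values were taken as linear intensity as deposited. Values of the missing-value code (-9999) were set to missing, values under the 10th percentile of the positive values (0.0854) were set to that floor, and log2 was taken. In all 10.0% of the CodeLink values lay below the floor, and 555 genes stood at it on every array. Array medians lay within 0.1 log2 units of each other on each platform (10.92 to 10.96 on Affymetrix), so values were used as deposited without further scaling. Of 10752 CodeLink probes 9998 were held by every group and analysed. The other 754 were empty in at least 1 group, 752 of them on all MPTP 7 d arrays, and 13 had a gene name. Within the analysed probes 165 values were missing codes and 5 were negative. Any 2 arrays had identical values for at most 0.409% of the probes on CodeLink and 0% on Affymetrix.

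Of 12654 Affymetrix probes 10298 had 1 gene symbol and were used, 363 had several and 1993 none. On CodeLink 8772 had 1 symbol, 321 several and 1659 none. Symbols were brought up to date by Entrez identifier for 10279 Affymetrix and 8729 CodeLink probes, by symbol for 6 and 15, and by synonym for 13 and 28. A gene was represented by the probe with the highest mean over all arrays, with at least 3 values per group. The gene table served only for names, from the GRCm38 annotation, and the array build is not given in the sources used here.

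Each platform was fitted with limma (lmFit, eBayes) with 1 mean per group and 3 contrasts, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Gene lists, 22 in number and fixed before the values were seen, were tested with camera at a preset correlation of 0.01 when at least 5 members were measured. They were tested again with the correlation estimated, which gave the larger p for every list that passed camera, and with fry. Adjusted p of lists was taken over the lists of a contrast. Some genes belong to more than 1 list, so list calls are not independent of each other. Psmb8 and Psmb9 are in the proteasome and interferon lists. Gbp2 is in the interferon and reactive astrocyte lists, and Cxcl10 in the cytokine and reactive astrocyte lists. Counts adjusted over the list alone used the members' own p-values. The SAM-type test was a moderated difference permuted between groups and written for this work. Sample numbers did not pair samples within a platform (correlations of samples sharing a number -0.50 to 0.36), so they were not modelled, and blocking on them was used as an alternative only. With 4 against 4 arrays 2.86% of unchanged genes separate completely by chance, and with 3 against 4 arrays 5.71%. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with matplotlib 3.10.9 and pandas 2.3.3 were used.

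Genes were named by a rule fixed beforehand. It took 6 dopamine genes where measured, the 8 largest changes in each direction with non-overlapping arrays, up to 4 per list with the smallest adjusted p, and up to 10 shared by the platforms. For 7 d against 24 h it took the 4 largest in each direction, or the 5 smallest p-values where fewer than 5 genes passed. The rule named 345 gene results. Of these 176 are given in the text, the choice among them was made after their values were seen, and 0 genes outside the rule are named there. For comparison, sample values of Nr4a2 on CodeLink and Cxcl10 on Affymetrix are given as well. Slc18a2 was not analysed here.

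In a self-test, changes were planted in simulated arrays with each gene's mean and residual spread. At log2 changes of 0.25, 0.5 and 1, limma recovered 59.7%, 83.6% and 100% for Affymetrix MPTP 24 h against saline, and 52.2%, 92.5% and 97.0% for MPTP 7 d. For CodeLink it recovered 10.4%, 37.3% and 83.3% at 24 h and 5.97%, 37.3% and 89.4% at 7 d. For 7 d against 24 h it was 50.7%, 92.5% and 100% on Affymetrix and 20.9%, 43.3% and 89.4% on CodeLink. The share of false calls was 4.40% to 9.73%. A list shifted by -0.3 was found in all 6 contrasts, with 1 unplanted list called on CodeLink for 7 d against 24 h and 0 elsewhere. The simulated genes were drawn independently, with the same spread in every group. The self-test therefore cannot tell how often lists of correlated genes, or groups of unequal spread, give false calls.

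Alternatives fixed beforehand were quantile normalization, median centring, leaving out dim genes, the mean of a gene's probes, trend and robust eBayes, floors at the 2nd and 25th percentile, blocking on sample number, fits of the 2 compared groups alone, the SAM-type test, an adjusted p under 0.10, camera with an estimated correlation, fry, and leaving out each array. Cyclic loess was added after the values were seen. The shared saline arrays were addressed by 50 simulated draws of unchanged groups and by dividing the saline arrays between the contrasts in all 6 ways. Group labels were also divided in the 35 possible ways for a contrast, or 100 for the overlap of the contrasts. An outlying array was looked for with Dixon's test in 355 groups of values, with a critical value of 0.829, where 17.75 were expected by chance. The values were those of the genes given in the text and each array's median, SD and mean correlation with its group.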

Results

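RNA from the mouse substantia nigra, the midbrain region that holds the dopaminergic neurons projecting to the striatum, was measured on 2 microarray platforms. Per the labels, male C57BL/6 mice aged 10 weeks had received 4 injections of MPTP at 30 mg/kg, or of saline. The text of CodeLink MPTP 24 h sample 1 breaks off after 2 injections and gives no dose, and Affymetrix MPTP 7 d samples 1 and 3 have no age. MPTP is a toxin whose oxidised product enters dopaminergic neurons through the dopamine transporter and inhibits complex I of the respiratory chain. Each sample was RNA from the pooled tissue of 6 mice. On Affymetrix arrays there were 4 saline samples, 4 MPTP samples taken at 24 h and 4 taken at 7 d. On CodeLink arrays there were 4 saline samples, 4 MPTP samples at 24 h and 3 at 7 d. The labels place the saline mice at either 24 h or 7 d without saying which, so saline formed 1 group per platform. The number of arrays limits the precision, and p-values measure the spread between pools. After naming, 8221 genes were tested on Affymetrix and 8582 on CodeLink, with 5505 on both.

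The first comparison asked which transcripts of the nigra differed 24 h after MPTP, and on Affymetrix several genes of dopamine handling fell. Slc6a3, the dopamine transporter, was 2.01-fold lower (log2 fold change -1.01 ± 0.13 SE, n = 4 and 4, adjusted p = 0.00074). Th, the rate-limiting enzyme of dopamine synthesis, was 1.66-fold lower (-0.73 ± 0.13, adjusted p = 0.0027). Aldh1a1, an aldehyde dehydrogenase of ventral nigral neurons, was 2.27-fold lower (-1.18 ± 0.22, adjusted p = 0.0035). Drd2, the dopamine autoreceptor, fell by 0.21 on the log2 scale and Nr4a2, a transcription factor of these neurons, fell by 0.30, whereas Ddc, which converts L-DOPA to dopamine, had a log2 fold change of 0.07 ± 0.05 (adjusted p = 0.25). Of 23 measured dopaminergic neuron genes 12 fell and 1 rose, and 12 and 1 adjusted over the list alone. The list's median log2 fold change was -0.14 (camera adjusted p = 0.0016, adjusted p = 0.23 with an estimated correlation).

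A number of inflammatory genes rose on the same arrays by small amounts. Iigp1, an interferon-inducible GTPase, was 1.37-fold higher (0.45 ± 0.06, n = 4 and 4, adjusted p = 0.00068), and the chemokines Ccl2, Ccl12 and Ccl3 were 1.26-fold, 1.20-fold and 1.16-fold higher. The immunoproteasome subunits Psmb8 and Psmb9 were 1.23-fold and 1.32-fold higher, Gbp2 1.17-fold, and the cytokine Il1a 1.20-fold. Of 23 interferon and antigen presentation genes 9 rose and 0 fell, 11 and 0 adjusted over the list alone (median 0.15, camera adjusted p = 0.00046, adjusted p = 0.23 with an estimated correlation). Of 24 cytokine and chemokine genes 9 rose and 1 fell, 12 and 1 adjusted over the list alone (median 0.16, camera adjusted p = 0.00060, adjusted p = 0.23 with an estimated correlation). Among 27 microglia and macrophage genes 9 rose and 0 fell, 9 and 0 adjusted over the list alone, including the surface proteins Cd52 (0.28) and Cd14 (0.20). Its camera adjusted p was 0.014, and the adjusted p = 0.40 with an estimated correlation. Among 22 reactive astrocyte genes 5 rose and 1 fell, also adjusted over the list alone, with Hspb1 at 0.32 and Serpina3n at 0.20 (camera adjusted p = 0.022, adjusted p = 0.34 with an estimated correlation). The gene that fell was Timp1, an inhibitor of matrix proteases (-0.15, adjusted p = 0.018). Under quantile normalization its log2 fold change turned to 0.06. On CodeLink the same gene rose at 24 h (2.03), so the platforms went opposite ways. Its saline values lay high on Affymetrix (14.37 to 14.44), whereas most were at the floor on CodeLink. Which platform reports the transcript was not tested.

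Part of the general neuronal, myelin, chaperone and respiratory chain genes fell on Affymetrix at 24 h. Among 19 general neuron and synapse genes 11 fell and 0 rose, 11 and 1 adjusted over the list alone (camera adjusted p = 0.0051, adjusted p = 0.23 with an estimated correlation). Nsf and Snap25 of the vesicle fusion machinery fell by 0.54 and 0.55, the dendritic protein Map2 by 0.61 and the enolase Eno2 by 0.61. Of 12 oligodendrocyte genes 7 fell and 1 rose, also adjusted over the list alone, with the myelin proteins Mag and Mog at -0.56 and -0.67 and the galactolipid enzyme Ugt8a at -0.95 (camera adjusted p = 0.013, adjusted p = 0.38 with an estimated correlation). Of 17 heat shock genes 8 fell and 1 rose, 10 and 1 adjusted over the list alone, among them the chaperones Hsph1 (-0.82) and Hspd1 (-0.46) (camera adjusted p = 0.013, adjusted p = 0.46 with an estimated correlation). Of 33 other respiratory chain and ATP synthase genes 15 fell and 2 rose, 19 and 2 adjusted over the list alone, among them Uqcrb of complex III (-0.74) and Atp5c1 of ATP synthase (-0.42) (camera adjusted p = 0.00060, adjusted p = 0.46 with an estimated correlation). Of 29 complex I genes 13 fell and 2 rose, 15 and 2 adjusted over the list alone, among them Ndufab1 (-0.38) and Ndufb11 (-0.46) (camera adjusted p = 0.012, adjusted p = 0.48 with an estimated correlation). Of 39 proteasome and ubiquitin genes 12 fell and 4 rose, 17 and 5 adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.48 with an estimated correlation). Of all 22 lists 11 passed, 4 higher and 7 lower, against 8, 4 and 4, under cyclic loess, where complex I, proteasome and oligodendrocyte genes did not pass. Complex I and proteasome genes also missed under quantile normalization and fry, general neuron, proteasome, reactive astrocyte and cytokine genes with dim genes left out, and Ndufab1 as the mean of its probes. The antioxidant enzyme Sod1 fell by 0.90 (adjusted p = 0.00022), the astrocyte pump subunit Atp1b2 by 0.88 and the astrocyte protein S100b, which did not pass with only the 2 groups fitted, by 0.80.

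Among the largest Affymetrix changes at 24 h were the microtubule kinase Mark2 at -1.50, the chromatin remodeller Smarca2 at -1.15 and the RNA helicase Ddx5 at -1.13. Plk4, a kinase of centriole duplication, was at 1.38, the cap-binding protein Eif4e at 1.06, and Fv1 and Rnf103 at 0.88 each. As the mean of a gene's probes Mark2 was at -0.57, Plk4 at 0.77, Eif4e at 0.52, Rnf103 at 0.28, Macroh2a1 at -0.21, Mag at -0.28, Atp1b2 at -0.46 and Nr4a2 at -0.16, and each of them still passed. In all, 2714 of 8221 genes passed the adjusted p of 0.05 in limma, 1107 higher and 1607 lower, of which 13 changed more than 2-fold. The other 11 lists, namely other neuron types, astrocyte, endothelial and vessel wall, blood with choroid plexus and ependyma, p53 and cell death, oxidative stress and metallothionein, unfolded protein and amino acid response, Parkinson disease, immediate early, glucocorticoid response and cell division genes, had camera adjusted p between 0.070 and 0.85. By fry 16 lists passed, 7 of them among these 11: cell division genes as higher, and p53, endothelial, other neuron type, unfolded protein, oxidative stress and astrocyte genes as lower (adjusted p 0.0040 to 0.048). The MPTP 24 h arrays correlated with each other at 0.980 to 0.991 on average per array, against 0.997 to 0.998 for saline, and their values had an SD of 1.43 log2 units against 1.49. With only the 2 groups in the fit 1661 genes passed, without saline sample 1, 2 or 3 the counts were 1717, 1797 and 1724, and under quantile normalization the split was 1393 higher and 1268 lower.

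**Figure D1:**
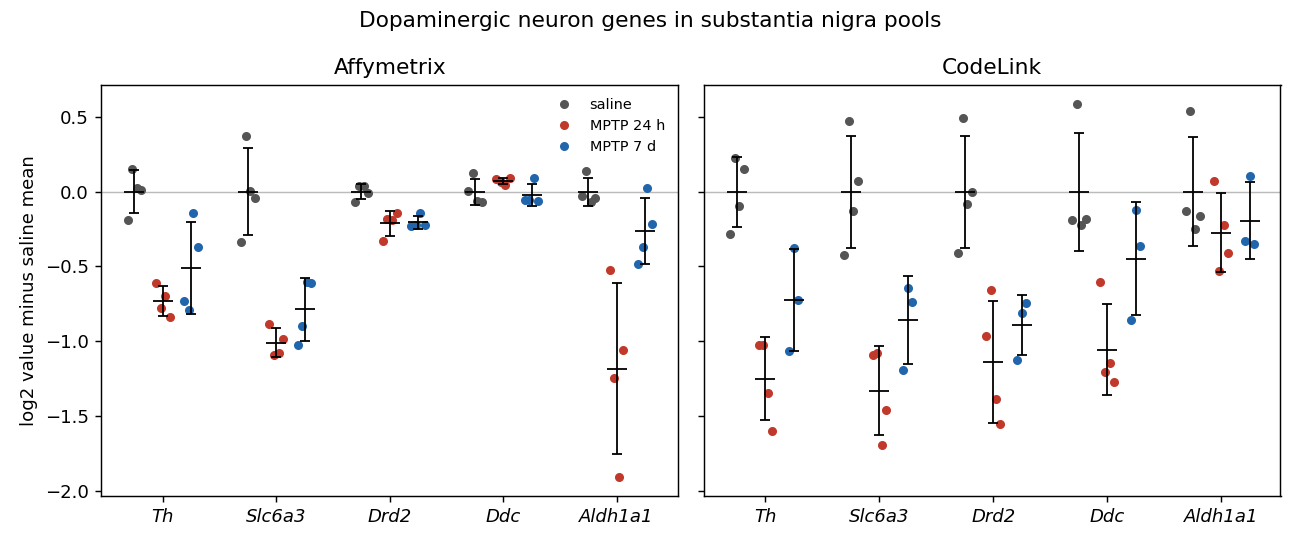
Log2 values of 5 dopamine genes minus the saline mean (vertical axis) on Affymetrix (left) and CodeLink (right), 1 point per pooled sample in saline (grey), MPTP 24 h (red) and MPTP 7 d (blue); the horizontal tick is the mean and the bar 1 SD. On both platforms every MPTP 24 h sample lay below every saline sample for Th, Slc6a3 and Drd2, whereas Ddc fell on CodeLink and Aldh1a1 on Affymetrix.

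On CodeLink arrays, several chemokine and interferon genes rose at 24 h by larger amounts. Cxcl10, an interferon-induced chemokine, was 9.83-fold higher (3.30 ± 0.34 SE, n = 4 and 4, adjusted p = 0.00056). The chemokines Ccl12 and Ccl3 were 2.99-fold and 2.76-fold higher (1.58 ± 0.18 and 1.47 ± 0.17), and Ccl7, at the floor in all 4 saline samples, was at least 2.07-fold higher. The interferon-induced genes Oasl2, Ifit1 and Gbp2 were 3.73-fold, 2.51-fold and 2.51-fold higher and Isg15 1.32-fold. Timp1, with 3 of 4 saline samples at the floor, was at least 4.09-fold higher (adjusted p = 7.8e-05), its log2 fold change running from 0.20 to 2.21 with the floor chosen. The glucan receptor Clec7a, with 1 saline sample there, was at least 4.2-fold higher, and Serpina3n 2.13-fold. Of 19 interferon and antigen presentation genes 12 rose and 0 fell, 15 and 0 adjusted over the list alone (median 0.67, camera adjusted p = 1.9e-05, adjusted p = 0.43 with an estimated correlation). Of 20 cytokine and chemokine genes 8 rose and 1 fell, 9 and 2 adjusted over the list alone (camera adjusted p = 0.0090, adjusted p = 0.35 with an estimated correlation). Of 23 microglia and macrophage genes 12 rose and 0 fell, 16 and 1 adjusted over the list alone, among them the receptor Tlr2 (1.11), the oxidase subunit Cyba (0.80), the complement component C1qa (0.71) and the adaptor Tyrobp (0.53). The list's median was 0.47 (camera adjusted p = 3.5e-05, adjusted p = 0.43 with an estimated correlation). Of 22 reactive astrocyte genes 7 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0090, adjusted p = 0.18 with an estimated correlation). With the floor at the 25th percentile Ccl7, Clec7a, Gbp2, Psmb9 and Timp1 no longer passed, and Ccl3 and Ifit1 stood at 0.75 and 0.83. On Affymetrix Cxcl10 lay near the low end of the scale, with saline values of 8.80 to 8.93. There its 24 h samples stood only 0.03 to 0.47 above the saline mean, overlapping saline (up to 0.08).

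Several dopaminergic genes fell on CodeLink too, with larger differences for Th, Slc6a3 and Drd2 than on Affymetrix. Among genes past the threshold, not all 5505 on both platforms, the median ratio of the absolute log2 fold changes, CodeLink to Affymetrix, was 1.76. Since these genes were chosen by their calls, the ratio is not a scale for all genes. Th was 2.38-fold lower (-1.25 ± 0.19, n = 4 and 4, adjusted p = 0.0032), Slc6a3 2.52-fold (-1.33 ± 0.22, adjusted p = 0.0048), Drd2 2.20-fold (-1.14 ± 0.24, adjusted p = 0.012) and Ddc 2.08-fold (-1.06 ± 0.24, adjusted p = 0.017, missing the threshold in 1 of 21 other settings at adjusted p = 0.057). The nicotinic receptor subunit Chrna4 fell by 1.10, and Aldh1a1 stood at -0.27 ± 0.21 (adjusted p = 0.38). Of 25 dopaminergic neuron genes 9 fell and 1 rose, 11 and 1 adjusted over the list alone (median -0.24, camera adjusted p = 0.0090, adjusted p = 0.58 with an estimated correlation). Of 20 general neuron and synapse genes 6 fell and 2 rose, 9 and 2 adjusted over the list alone (camera adjusted p = 0.041, adjusted p = 0.43 with an estimated correlation). Nsf, the growth-associated Stmn2 and the vesicle protein Sv2a fell by 0.71, 0.81 and 0.64, while the synapsin Syn2 was at 0.53 and did not pass as the mean of its probes. Of 15 oligodendrocyte genes 3 fell and 0 rose, 4 and 0 adjusted over the list alone, namely the transcription factor Olig1 (-0.46), the iron carrier Trf (-0.44) and Ugt8a (-0.80) over all genes (camera adjusted p = 0.0090, adjusted p = 0.58 with an estimated correlation). Without MPTP 24 h sample 3, Trf and Ugt8a did not pass, and 1240 genes in all did.

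The proteasome and ubiquitin list passed camera at 24 h in opposite directions on the platforms, as lower on Affymetrix and as higher on CodeLink. Of 33 such genes 9 rose and 1 fell on CodeLink, 9 and 1 adjusted over the list alone (median 0.17, camera adjusted p = 0.013, adjusted p = 0.80 with an estimated correlation). The ATPase subunit Psmc6 was at 0.85, the core subunits Psmb3 and Psmb9 at 0.49 and 0.97, and the regulatory subunit Psmd2 at -0.47. The respiratory chain lists did not pass there, with 1 higher and 0 lower of 23 other respiratory chain genes and 2 higher and 1 lower of 18 complex I genes. The largest CodeLink changes at 24 h also held Tnp1, a chromatin protein of spermatids (3.39 ± 0.93, 1 saline sample at the floor), the polyamine enzyme Sat1 (2.87 ± 0.51), the guanine deaminase Gda (2.84 ± 0.77), Gnai2, an inhibitory G protein subunit (-2.57 ± 0.10), Jkamp (-2.14) and Zbtb4 (-1.95). Tnp1 and Gda, at adjusted p = 0.033 and 0.031, each missed the threshold in 7 of 21 other settings, with adjusted p up to 0.154 and 0.079. The tau gene Mapt was at 1.48, Bdnf at 0.72, the immediate early factors Fos and Junb at -0.92 and 0.96, Sod1 at -0.40 and the endothelial receptor Kdr at -1.37. In limma 1882 of 8582 genes passed, 886 higher and 996 lower (1103 and 989 with the floor at the 2nd percentile), 176 of them changed more than 2-fold. The 13 other tested lists had camera adjusted p between 0.14 and 0.76, though by fry, which 10 lists passed, cell division, immediate early and glucocorticoid response genes passed as higher (adjusted p = 0.00098, 0.040 and 0.040), and the blood list, with 3 measured genes, was not tested. General neuron and proteasome genes did not pass without the 2 arrays of doubtful text, proteasome genes under fry, and general neuron, reactive astrocyte and cytokine genes with dim genes left out, where immediate early genes passed instead. No list call of MPTP against saline, on either platform or at either time, held with an estimated correlation.

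**Figure D2:**
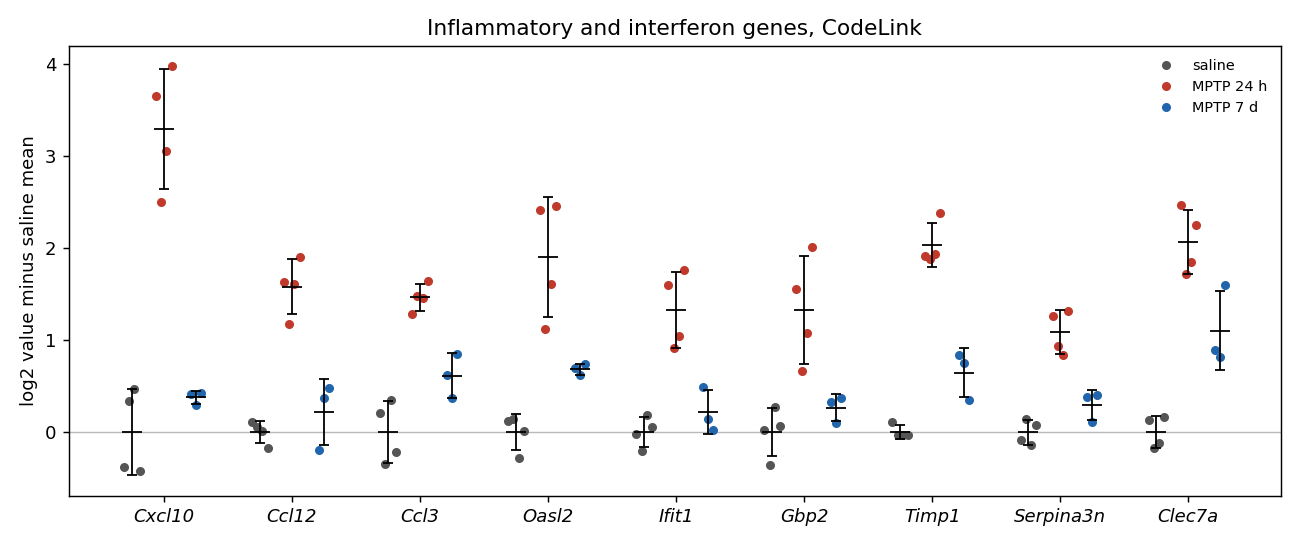
CodeLink log2 values of 9 inflammatory and interferon genes minus the saline mean (vertical axis), 1 point per pooled sample in saline (grey, n = 4), MPTP 24 h (red, n = 4) and MPTP 7 d (blue, n = 3); the horizontal tick is the mean and the bar 1 SD. Every MPTP 24 h sample lay above every saline sample, with Cxcl10 at a mean difference of 3.30, and 3 of the 4 saline values of Timp1 are the floor.

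Across the 5505 genes on both platforms, 425 passed at 24 h on both in the same direction, 131 higher and 294 lower, and 101 passed in opposite directions. With dim genes left out, 41 higher and 266 lower were shared. Independent lists of these lengths would share 213.2, which leaves out of account any pool measured on both platforms. The shared genes included Th, Slc6a3, Mark2 (-1.50 on Affymetrix and -1.24 on CodeLink), the nucleic acid binding protein Pura (-0.97 and -1.17), the histone Macroh2a1 (-0.74 and -1.41) and the kinase subunit Csnk2a1 (0.45, or 0.19 as the mean of probes, and 1.86). Gnai2, at -2.57 on CodeLink, was at -0.33 on Affymetrix, where it missed the threshold in 4 of 19 other settings, with adjusted p up to 0.20. The log2 fold changes correlated across genes, which are not independent replicates, at Pearson's r = 0.26. Without saline sample 1 or 3 on both platforms the shared count was 244 or 269.

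The second comparison asked what differed at 7 d. On Affymetrix Slc6a3 was 1.72-fold lower (-0.79 ± 0.13 SE, n = 4 and 4, adjusted p = 0.0070). Ret, the receptor for glial neurotrophic factors, fell by 0.55 (adjusted p = 0.0045) and Nr4a2 by 0.26, while Th stood at -0.51 ± 0.13 (1.42-fold lower, adjusted p = 0.045), Drd2 at -0.20 (adjusted p = 0.028) and the nicotinic subunit Chrna6 at -0.19. Aldh1a1 (-0.26 ± 0.22, adjusted p = 0.61) and Ddc (-0.02 ± 0.05, adjusted p = 0.90) did not pass. Of 23 dopaminergic neuron genes 9 fell and 0 rose, 15 and 0 adjusted over the list alone (median -0.15, camera adjusted p = 2.3e-06, adjusted p = 0.15 with an estimated correlation). Th missed the threshold in 13 of 19 other settings, with adjusted p up to 0.126, and Drd2 in 8, up to 0.088.

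Other Affymetrix genes also differed at 7 d. The astrocyte water channel Aqp4 was 1.72-fold higher (0.79 ± 0.12, n = 4 and 4, adjusted p = 0.0040), whereas Atp1b2 fell by 0.95 and Sod1 by 0.60. Mapt and the neurotrophin Bdnf were at 0.44 and 0.43, the NF-kappaB inhibitor Nfkbia at -0.31, Nsf at -0.35, Map2 at -0.41 and Timp1 at -0.17, opposite in sign to CodeLink (0.65). The largest differences were the phosphatase Inpp4a (1.51), the fucosyltransferase Fut9 (1.17), the chromatin protein Cbx3 (1.06), the cell cycle inhibitor Cdkn1b (1.05), Klhl9 (0.98) and the RNA helicase Ddx6 (0.87), against Mark2 (-1.06), the transcription factor Nfix (-1.03) and Pura (-0.75). Csnk2a1 was at 0.56. As the mean of probes Mark2 was at -0.51, Nfix at -0.49, Cdkn1b at 0.62, Atp1b2 at -0.56 and Csnk2a1 at 0.23, and each of them still passed. Map2, Timp1 and Ndufa12 missed the threshold in 13, 14 and 10 of 19 other settings, Bdnf and Chrna6 in 5 and 4, and Mapt and Nfkbia in 1 each. Complex I, proteasome, and interferon and antigen presentation genes each passed camera as higher at adjusted p = 0.034, with adjusted p = 0.70 for each with an estimated correlation. Their medians were 0.06, 0.03 and 0.03, and none of them passed fry, where p53 and cell death genes did as lower (adjusted p = 0.044). The only complex I gene past the threshold fell (Ndufa12, -0.18), and 0 of 39 proteasome and 0 of 23 interferon genes passed, over all genes and adjusted over the list alone alike. Their members with the smallest p were Psmd3 at -0.20 and Psmc3 at 0.22 (adjusted p = 0.054 and 0.072), and Iigp1 at 0.19 and B2m at 0.37 (adjusted p = 0.093 and 0.17). With only the 2 groups fitted all 4 passed (adjusted p = 0.0048, 0.013, 0.021 and 0.0099), as did Mpeg1 (0.049), and without MPTP 24 h sample 3 all of these except Iigp1. Microglia and macrophage genes passed camera at adjusted p = 0.046 (adjusted p = 0.70 with an estimated correlation) with 0 of 27 members past the threshold in either count, Mpeg1 at 0.16 and Laptm5 at -0.15. The other 17 lists had camera adjusted p from 0.084 to 0.87.

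In limma 368 of 8221 Affymetrix genes passed at 7 d, 86 higher and 282 lower. The count was 1267 with only the 2 groups fitted, 1286 by the SAM-type test, 855 without MPTP 24 h sample 3, 233 under quantile normalization, 34.3% of them higher against 23.4% above, and 268 (103 higher and 165 lower) under cyclic loess. Without any 1 of the saline samples it was 205, 200, 173 and 167, and without any 1 of the MPTP 7 d samples 186, 158, 190 and 215.

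On CodeLink at 7 d, dopaminergic genes stood lower with adjusted p near the threshold. Th was at -0.72 ± 0.21 SE (1.65-fold lower, n = 3 and 4, adjusted p = 0.039), Slc6a3 at -0.86 ± 0.24 (adjusted p = 0.037) and Drd2 at -0.89 ± 0.26 (adjusted p = 0.042). Chrna4 fell by 1.00 (adjusted p = 0.0059) and Dlk1, a growth regulator, by 1.15, the transcription factor Lmx1b was at 0.71, and Ddc (-0.45 ± 0.26, adjusted p = 0.26) and Aldh1a1 (-0.19 ± 0.22, adjusted p = 0.59) did not pass. Of 25 dopaminergic neuron genes 6 fell and 1 rose, as many adjusted over the list alone, and the list did not pass camera (adjusted p = 0.26). Th missed the threshold in 9 of 21 other settings, with adjusted p up to 0.124, Slc6a3 in 10, up to 0.125, and Drd2 in 11, up to 0.144. Each of these genes missed it without the 7 d array of sample 2, whose protocol text names 24 h. Each also missed it without the 7 d array of sample 4.

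Some inflammatory genes were still higher on CodeLink at 7 d: Isg15 was 1.58-fold higher (0.66 ± 0.08, n = 3 and 4, adjusted p = 0.0015), Cd14 1.86-fold, Cyba 1.43-fold and Timp1, with 3 of 4 saline samples at the floor, at least 1.56-fold. Timp1, Cyba and Cd14 missed the threshold in 6, 4 and 2 of 21 other settings, all 3 of them without the 7 d array of sample 3, and with the floor at the 25th percentile the log2 fold change of Timp1 was 0. Of 23 microglia and macrophage genes 6 rose and 0 fell, 7 and 0 adjusted over the list alone, and of 19 interferon and antigen presentation genes 1 rose and 1 fell, also adjusted over the list alone. Aqp4 was at 0.76 and the astrocyte genes Atp1b2, Sox9 and Slc1a3 at -1.57, -1.46 and -0.63. Nsf and Stmn2 both fell by 0.83 and Sod1 by 0.49, Syn2 was at 0.46 and turned to -0.07 as the mean of its probes. Fos was at -0.98, Nfkbia at -0.63 and Bdnf at 0.59. Aqp4, Prkaca and Dlk1 each missed the threshold in 3 of 21 other settings, Nfkbia in 4, Bdnf and Sod1 in 1, and Lmx1b in 1. That setting was the floor at the 25th percentile, where the log2 fold change of Lmx1b was 0. Over the other settings that of Cd14 ranged from 0.30 to 1.10. The largest changes were Gnai2 (-2.68 ± 0.11), the growth factor Hdgf (-2.29 ± 0.20, and -1.30 with the floor at the 25th percentile), Csnk2a1 (2.23 ± 0.18), Zbtb4 (-2.04 ± 0.22), Eid1 (1.91 ± 0.21), the signalling inhibitor Spry2 (1.88 ± 0.22), the kinase subunit Prkaca (-1.82 ± 0.36) and Mapt (1.68 ± 0.19). In limma 1799 of 8582 genes passed, 955 higher and 844 lower, the larger share turning to lower under quantile normalization (827 higher and 899 lower), cyclic loess (927 and 986), with dim genes left out (603 and 766) and with the floor at the 25th percentile (649 and 741). Of the 21 tested lists 0 passed camera (adjusted p 0.12 to 0.95), and 2 passed fry, general neuron and synapse genes and cell division genes, while 3 passed camera under quantile normalization, general neuron, microglia and proteasome genes. The protocol text of the MPTP 7 d array of sample 2 names 24 h where its title names the 7 d group, and that of the 24 h array of sample 1 is incomplete. Without both arrays 1149 genes passed, and without the 7 d array of sample 2 or 3 alone 1159 or 748.

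At 7 d, 113 genes passed on both platforms in the same direction, 16 higher and 97 lower, where independent lists, with the same reserve, would share 26.6, and 9 passed in opposite directions. They included Csnk2a1 (0.56 on Affymetrix and 2.23 on CodeLink), Atp1b2 (-0.95 and -1.57), Mark2 (-1.06 and -1.47), Ddx6 (0.87 and 1.46), Mapt (0.44 and 1.68), Pura (-0.75 and -1.17) and Inpp4a (1.51 and 0.42), which missed the threshold on CodeLink in 13 of 21 other settings. Of the Affymetrix calls 84.8% had the same sign on CodeLink, and of the CodeLink calls 62.9% on Affymetrix, against 58.3% over all 5505 genes. Leaving out samples of the same number on both platforms moved the count to between 48 and 170, and under quantile normalization it was 73.

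**Figure D3:**
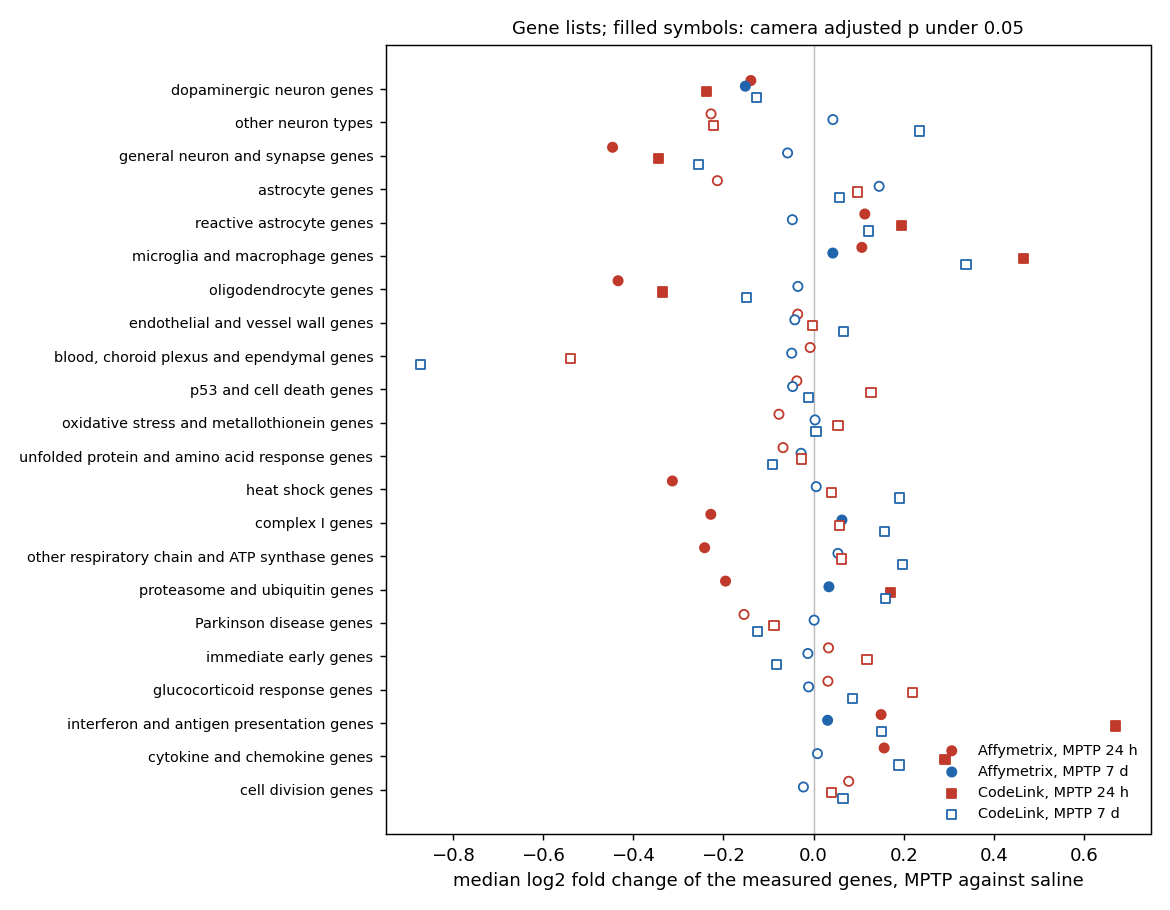
Median log2 fold change of the measured genes of each list against saline (horizontal axis) for the 22 lists (vertical axis), circles for Affymetrix and squares for CodeLink, red at 24 h and blue at 7 d; filled symbols mark camera adjusted p under 0.05. Interferon and antigen presentation genes on CodeLink at 24 h stood at 0.67, and the respiratory chain and heat shock lists lay below 0 at 24 h on Affymetrix alone.

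The third comparison set 7 d against 24 h directly. On Affymetrix 2313 of 8221 genes passed in limma, 1233 higher and 1080 lower at 7 d. The phosphatase subunit Ppp1cb was 3.21-fold higher at 7 d than at 24 h (1.68 ± 0.32 SE, n = 4 and 4, adjusted p = 0.0077), Smarca2 2.57-fold, the amino acid transporter Slc38a2 2.52-fold and the sterol enzyme Sc5d 2.44-fold. Lower at 7 d were Rnf103 (-0.65), Fv1 (-0.57), Trgv4 (-0.55) and Klk1b5 (-0.51, adjusted p = 0.041). Among lists, 19 of 29 complex I genes were higher and 2 lower at 7 d, 19 and 4 adjusted over the list alone (median 0.39, camera adjusted p = 3.1e-05, adjusted p = 0.38 with an estimated correlation). In all 13 lists passed camera, 9 higher and 4 lower at 7 d, and 0 with an estimated correlation (smallest adjusted p = 0.31). Besides complex I these were other respiratory chain, proteasome, heat shock, astrocyte, oligodendrocyte, general neuron, other neuron type and oxidative stress genes as higher, and reactive astrocyte, cytokine, interferon and cell division genes as lower. The other 9 lists had camera adjusted p from 0.059 to 0.85. Klk1b5, Trgv4 and Rnf103 missed the threshold in 12, 4 and 2 of 19 other settings and Fv1 and Slc38a2 in 1 each. With only the 2 groups fitted 618 genes passed, with dim genes left out 1533, and without MPTP 24 h sample 2 or MPTP 7 d sample 2, 3 or 4 the counts were 1291, 1408, 1120 and 1049. The split was 1110 higher and 1154 lower under quantile normalization, 1398 and 777 under median centring and 1306 and 622 under cyclic loess.

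On CodeLink 0 of 8582 genes passed in limma between 7 d and 24 h, with 584 at an unadjusted p under 0.05 and 21 by the SAM-type test. The smallest p belonged to Timp1 (-1.39 ± 0.15, n = 3 and 4, adjusted p = 0.057; -0.20 with the floor at the 25th percentile, adjusted p = 0.99), the galectin Lgals9 (-0.72, adjusted p = 0.057), Cxcl10 (-2.92 ± 0.36, adjusted p = 0.072), the chemokine Cxcl16 (-0.85, adjusted p = 0.099) and the lymphocyte receptor gene Klrd1 (0.40, adjusted p = 0.099). As lists, reactive astrocyte genes (median -0.12, camera adjusted p = 3.4e-06) and cytokine and chemokine genes (median -0.13, camera adjusted p = 2.2e-07) were lower at 7 d, and both calls held with an estimated correlation (adjusted p = 0.012 and 0.016). Adjusted over the list alone, 6 of 22 and 4 of 20 genes were lower and 0 higher. Interferon and antigen presentation genes had a median of -0.58 (camera adjusted p = 9.8e-14, adjusted p = 0.13 with an estimated correlation), with 11 of 19 lower and 1 higher adjusted over the list alone. Microglia, immediate early and glucocorticoid response genes also passed camera as lower, and dopaminergic, oligodendrocyte, complex I and other respiratory chain genes as higher, with adjusted p = 0.13 to 0.72 with an estimated correlation. The other 11 lists had camera adjusted p from 0.13 to 0.77. In limma 12 genes passed with the floor at the 25th percentile, and 9 without MPTP 24 h sample 2. Of 21 other settings each, Lgals9 passed in 6, Timp1 and Cxcl10 in 5, Cxcl16 in 3 and Klrd1 in 2.

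Both MPTP contrasts share the saline arrays, so part of any likeness between them is built in. On CodeLink 1259 genes passed at both times in the same direction, 580 higher and 679 lower, among them Gnai2, Csnk2a1, Mapt and Chrna4. Independent lists, which leave the shared saline arrays out of account, would share 98.6 and 98.0. With the saline arrays divided between the contrasts, 462 to 701 genes were shared. The log2 fold changes correlated at r = 0.85 across genes, against 0.46 simulated, with a covariance of 0.120 against 0.0125, and with the arrays so divided r was 0.62 to 0.78. On Affymetrix 271 genes passed at both times in the same direction, 43 higher and 228 lower, among them Slc6a3, Th, Mark2 and Sod1, with 11.6 and 55.1 for independent lists. There r was 0.31 against 0.50 simulated, the covariance 0.0081 against 0.0030, and with divided saline arrays r was 0.13 to 0.39 and 45 to 90 genes were shared. The CodeLink count was 773 without both arrays of doubtful text and 679 without MPTP 7 d sample 3, and the Affymetrix count was 175 (52 higher and 123 lower) under quantile normalization and 193 (51 and 142) under cyclic loess. Without MPTP 24 h sample 3 the Affymetrix count was 514, and without any 1 saline or MPTP 7 d sample it was 120 to 163.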

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

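Among the tests in this part, those leaving out 1 Affymetrix array, dividing the saline or Affymetrix arrays and counting the same sign on the other platform were chosen after the result was seen, and cyclic loess after the range of the arrays was seen. By Dixon's test 1 array lay apart in 22 of 355 groups of values, where 17.75 were expected by chance. On Affymetrix in saline these were Sod1 at 13.67 and Chrna6 at 11.30 in sample 4, Serpina3n at 12.72 and Mapt at 14.90 in sample 3, and Psmd3 at 12.87 in sample 1. In MPTP 24 h sample 4 Map2 stood at 11.92. In MPTP 7 d sample 3 Drd2 stood at 11.41, Ddc at 10.92, Nr4a2 at 9.97, Gnai2 at 14.95 and Psmd3 at 12.55, and in sample 2 Eno2 at 14.02. On CodeLink in saline sample 2 Aldh1a1 stood at 4.30, Ddc at 3.62, Trf at 5.22 and Cd14 at -1.66, Timp1 at -3.40 in sample 1 and Sod1 at 4.17 in sample 4. In CodeLink MPTP 24 h Ccl7 stood at -3.03 in sample 1, Timp1 at -1.13 in sample 4, and Mark2 at -0.13 and Spry2 at 0.45 in sample 2. All these arrays were kept.

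Gene lists passed camera between the MPTP times at its preset correlation, 13 on Affymetrix and 10 on CodeLink. With an estimated correlation 0 of the 13 passed (smallest adjusted p = 0.31) and 2 of the 10, reactive astrocyte and cytokine genes (adjusted p = 0.012 and 0.016). On Affymetrix the median log2 difference of 7 d against 24 h was 0.39 for complex I, 0.28 for other respiratory chain, 0.23 for proteasome, 0.28 for heat shock, 0.36 for astrocyte, 0.37 for oligodendrocyte, 0.26 for general neuron, 0.30 for other neuron type and 0.059 for oxidative stress genes. It was -0.14 for reactive astrocyte, -0.13 for interferon, -0.10 for cytokine and -0.12 for cell division genes. On CodeLink it was 0.11 for dopaminergic, 0.15 for oligodendrocyte, 0.14 for complex I and 0.13 for other respiratory chain genes. It was -0.12 for reactive astrocyte, -0.14 for microglia, -0.12 for immediate early, -0.16 for glucocorticoid response, -0.58 for interferon and -0.13 for cytokine genes.

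Of the 2313 Affymetrix genes past the threshold between the MPTP times, only those given in the text follow, as log2 differences of 7 d against 24 h. Many were named for a change against saline on the same MPTP arrays, so part of a return towards saline is built in. Neuronal and glial genes stood at 0.92 for Aldh1a1, 0.55 for Snap25, 0.39 for Eno2, 0.47 for Mag, 0.67 for Mog, 0.71 for Ugt8a, 0.63 for S100b, 0.64 for Aqp4, 0.27 for Mapt and 0.27 for Bdnf. Stress and respiratory genes stood at 0.65 for Hsph1, 0.44 for Hspd1, -0.27 for Hspb1, 0.30 for Sod1, 0.56 for Atp5c1, 0.42 for Ndufab1, 0.41 for Ndufb11, -0.32 for Ndufa12 and 0.39 for Psmc3. Inflammatory genes stood at -0.26 for Iigp1, -0.18 for Gbp2, -0.22 for Psmb8, -0.37 for Psmb9, -0.37 for Ccl2, -0.26 for Ccl12, -0.21 for Ccl3, -0.24 for Il1a, -0.29 for Cd52, -0.23 for Serpina3n and 0.41 for B2m. Others stood at 1.68 for Ppp1cb, 1.36 for Smarca2, 1.33 for Slc38a2, 1.29 for Sc5d, 1.11 for Fut9, 1.01 for Inpp4a, 0.81 for Ddx5, 0.71 for Cbx3, 0.63 for Cdkn1b, 0.62 for Klhl9, 0.30 for Gnai2, 0.26 for Ddx6, 0.21 for Pura, -0.65 for Rnf103, -0.57 for Fv1, -0.55 for Trgv4 and -0.51 for Klk1b5.

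The first pattern weighed was the spread of the Affymetrix MPTP 24 h arrays, which correlated less with each other than the saline arrays and held 2714 genes past the threshold against saline. Sample 3 made up much of the spread, but without it the other 3 arrays still correlated at 0.9934 to 0.9951 on average, against 0.9977 to 0.9983 for saline over all probes, which argues against that array as the whole source. The fold changes did trend with signal level (r = -0.32 across genes, against -0.022 at 7 d), which could also make such a list. After cyclic loess 2572 genes passed, which argues against the trend as the whole source of the gene count, but the lists passing as lower went from 7 to 4.

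The second pattern was the fall of respiratory chain genes on Affymetrix at 24 h. Of the 28 called lower there, 16 were measured on CodeLink, 7 of them higher. Their median was -0.38 on Affymetrix and -0.025 on CodeLink, with an interval of -0.21 to 0.08, so whether the fall was carried by the RNA pools or could lie in the Affymetrix arrays stays undecided.

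The third pattern was the likeness of the CodeLink changes at 24 h and 7 d. Shared saline arrays could make it, but with the saline arrays divided between the contrasts the lowest correlation was 0.618, which argues against that as the whole source. Of 859 such genes 67.1% had the same sign on Affymetrix at 7 d, against 58.3% over all genes. In divisions of the Affymetrix arrays 2 of 35 gave a share as far from even, the highest other being 68.8%, so a difference arising on the CodeLink arrays alone stays open. Handling that differed between saline and MPTP pools could reach both platforms, where the share at 24 h was 65.7%, and also stays open.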

How the results depend on the processing

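Of the tests in this part, cyclic loess, leaving out arrays of doubtful text from lists and overlaps, and leaving out 1 array for the shared counts were chosen after the result was seen. Over other settings 91 of 128 values of the counts stayed the same within a factor of 1.5 and 37 moved, 21 higher and 16 lower, and the cause was not tested. Of the 3520 values of 176 gene results 3293 stayed the same, 191 were weaker, 32 stronger and 4 reversed, with 121 results the same throughout and 3516 values not reversed. Among the 3516 are log2 fold changes of 0, as for Ccl7, Lmx1b and Psmb9 on CodeLink with the floor at the 25th percentile. The reversals were Timp1 on Affymetrix at 24 h (0.057, quantile normalization), Ddc on Affymetrix at 7 d (0.0038, cyclic loess, and 0.021, without saline sample 2, with -0.056 without MPTP 7 d sample 3) and Syn2 on CodeLink at 7 d (-0.068, mean of probes). For Affymetrix genes at 7 d the count of 368 became 233 under quantile normalization, 180 with blocking on sample number, 1267 with the 2 groups alone and 1286 by the SAM-type test. At 24 h it became 1661 with the 2 groups alone. For 7 d against 24 h it became 1533 without dim genes and 618 with the 2 groups alone. The Affymetrix overlap of the times was 175 under quantile normalization, 140 with blocking and 438 at an adjusted p under 0.10. Affymetrix lists at 24 h were 7 without dim genes and 0 with an estimated correlation, and at 7 d 0 with an estimated correlation and 2 by fry. CodeLink genes for 7 d against 24 h were 4 under quantile normalization, 2 under median centring, 3 without dim genes, 7 under cyclic loess, 11 with the floor at the 2nd percentile, 12 with the floor at the 25th, 7 without the arrays of doubtful text and 21 by the SAM-type test. CodeLink lists at 7 d were 3 under quantile normalization, 2 without dim genes, 2 with blocking, 2 under cyclic loess, 1 without the arrays of doubtful text and 2 by fry, and at 24 h 0 with an estimated correlation. CodeLink genes at 7 d were 1149 and the CodeLink overlap 773 without the arrays of doubtful text, and that overlap was 1891 at an adjusted p under 0.10. Genes shared by the platforms at 7 d were 73 under quantile normalization, 57 with blocking, 197 at an adjusted p under 0.10 and 184 without Affymetrix MPTP 24 h sample 3 alone, and at 24 h 676 at an adjusted p under 0.10. Ddc on CodeLink at 24 h did not pass with blocking. Blocking gave 2195 Affymetrix and 1602 CodeLink genes at 24 h. Leaving out 1 array at a time gave 1717 to 3333 Affymetrix genes at 24 h, 158 to 855 at 7 d and 1049 to 3075 between the times, with 120 to 514 in the overlap. On CodeLink it gave 1240 to 1874, 748 to 2008 and 0 to 9, with 679 to 1376 in the overlap. Lists ranged from 10 to 12 and 1 to 7 on Affymetrix and 6 to 8 and 0 to 3 on CodeLink. Leaving out a sample of the same group and number on both platforms at once gave 244 to 467 shared genes at 24 h and 48 to 170 at 7 d.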

Other observations

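Among the tests in this part, the ribosomal protein genes, the use of sample numbers across platforms, and all tests of the doubtful array but the interferon one were chosen after the result was seen. Dividing the arrays of 2 groups in every possible way asked whether the counts could come from chance. For Affymetrix MPTP 24 h, MPTP 7 d and 7 d against 24 h the real counts of 2714, 368 and 2313 were reached in 1 of 35 divisions each, the real one, with a highest other count of 0. This is the smallest share that 35 divisions allow, so it argues against chance only at that resolution, for each contrast alone. The divisions cannot tell MPTP from handling that followed the groups. For CodeLink MPTP 24 h and MPTP 7 d the real 1882 and 1799 were reached in 1 of 35, with highest other counts of 26 and 331. For CodeLink 7 d against 24 h (highest other 16) and CodeLink lists at 7 d (highest other 8) the real count was 0, which 35 of 35 divisions reach by construction, so nothing was tested. For the other lists chance cannot be excluded. On Affymetrix 2 of 35 divisions reached the real 11 at 24 h (highest other 11) and 10 of 35 the real 5 at 7 d (highest other 8), and on CodeLink 3 of 35 reached the real 8 at 24 h (highest other 11). For the overlap of the times 1 of 100 reached the real 271 on Affymetrix (highest other 0) and 1 of 100 the real 1259 on CodeLink (highest other 9). For genes shared by the platforms 1 of 35 reached the real 425 at 24 h and 1 of 35 the real 113 at 7 d, both with a highest other of 0. The other divisions gave 0 genes on Affymetrix, so their shared count was 0 by construction. That comparison therefore adds nothing on the agreement between the platforms.

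The MPTP 7 d array of sample 2 on CodeLink, whose protocol text names 24 h, might in truth be a 24 h array. Its mean over interferon genes was 0.123 above saline, against 0.327 to 1.10 on the 24 h arrays and 0.119 and 0.241 on the other 7 d arrays. It lay below the lowest 24 h array by less than the SD of those arrays (0.36), so that test decided nothing. Of 32 inflammatory genes higher at 24 h, chosen without the 7 d arrays, it lay below the lowest 24 h array by more than their SD in 37.5%, but a held-out 24 h array reached 45.5% and the undoubted 7 d arrays 34.4% and 25%, so the test does not separate the times. On the 50 genes that best parted the times without it, scored 1 at the 24 h mean and -1 at the 7 d mean, it scored -0.137, against 0.0214 to 0.572 for held-out 24 h arrays (SD 0.27) and -0.873 and -0.307 for the other 7 d arrays. Single inflammatory genes with large changes at 24 h placed it with the 7 d arrays: Cxcl10 stood at -1.73 (24 h arrays 0.36 to 1.84, other 7 d arrays -1.84 and -1.71), Ccl12 at -0.96 (0.40 to 1.13, and -0.40 and -0.30) and Timp1 at -2.67 (-1.63 to -1.13, and -2.76 and -3.17). Some dopamine genes placed it with the 24 h arrays. Th stood at 2.76 (2.22 to 2.80, and 3.45 and 3.10), Slc6a3 at 2.81 (2.31 to 2.93, and 3.36 and 3.27) and Ddc at 2.17 (1.76 to 2.43, and 2.91 and 2.67). The inflammatory genes go against a 24 h pool, whereas low Th and Slc6a3 do not by themselves mark one. Affymetrix MPTP 7 d samples 1 and 2 stood at -0.73 and -0.79 against saline for Th (24 h arrays -0.61 to -0.84). For Slc6a3 they stood at -1.02 and -0.90 (24 h arrays -0.88 to -1.09). Samples 3 and 4 stood higher, at -0.14 and -0.37 for Th and -0.61 each for Slc6a3. Ddc did not fall on Affymetrix at 24 h, so it could not be compared. As single genes picked after the values were seen, the inflammatory and dopamine genes do not settle it. Across platforms, with the group means removed, the array correlated best with Affymetrix MPTP 7 d sample 2 (r = 0.486, highest other 0.379). The label of that Affymetrix array names 7 d. The labels do not state that the pools are shared, so the question stays open.

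Ribosomal protein genes, which belong to no list above, stood higher on CodeLink. Of 33 measured, 31 were above 0 at 24 h and 32 at 7 d, with medians of 0.30 and 0.34, and 12 and 16 passed as higher with 0 lower. Under quantile normalization the medians were 0.25 and 0.23. On Affymetrix the medians were -0.04 and 0.02, and 14 and 23 genes were above 0. There only 20 of the 33 lay under 14 log2 units, on a scale that ended at 15.44, and the medians of these 20 were 0.04 and 0.01.

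Samples of the same number were alike across platforms. Over 1723 genes, with the group means removed, each of the 11 CodeLink arrays correlated better with the Affymetrix array of its own number than with the others of its own group (mean r = 0.32, range 0.14 to 0.49). Over the arrays of all groups MPTP 24 h sample 3 did not, at 0.136 against 0.166 for MPTP 7 d sample 2. In an exact permutation test the real assignment was the best of 13824 (permutation p = 7.2e-05). The labels do not state that the pools are shared.

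The CodeLink probes empty on the MPTP 7 d arrays allowed a comparison of saline and MPTP 24 h for 725 of them. In limma 0 passed, 37 had an unadjusted p under 0.05, and the smallest adjusted p was 0.154, with 87.3% of their values at the floor.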
